A study of Mus musculus with 4 samples.

How the data were processed

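RNA sequencing counts of 4 mouse pancreas libraries were analysed, 2 labelled Pdx1-Cre with 1 floxed poh1 copy (control) and 2 labelled Pdx1-Cre with both copies floxed (knockout). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned and treated with DNase, and made into libraries with a VAHTS Universal V6 kit. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.6, STAR 2.7.6a, SAMtools 1.7 and featureCounts 2.0.1 were used with GRCm38. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The deposited values are whole-number counts per gene symbol, not normalised, per the file headers and the values themselves, with 1 file per library. Reads that fit near-identical genes (trypsinogens, amylases, globins, immunoglobulin segments) may have been split or dropped, and reads of overlapping or antisense genes cannot be told apart without the strand setting, so single members of such families are uncertain.

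Each file lists 55291 gene symbols, 53292 of which are in GENCODE release M21 on GRCm38, used here for gene types and coordinates. Total counts per library were 22875618, 24635792, 27470926 and 27849730. With these depths 1 count equals 0.0342 to 0.0455 CPM, and intervals from counts cover counting error only. Replicates were compared before they were combined: Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.98 within controls, 0.971 within the libraries labelled knockout and 0.907 to 0.921 between groups. A chi-square of counts per degree of freedom was 46.2 and 32.5 within groups and 141 to 190 between them, so no library was a copy of another. The first principal component held 76.4% of the variance and the second 13.5%.

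Differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, which left 19134 genes, TMM factors (0.962, 0.971, 1.02 and 1.05), the quasi-likelihood F test with group as the only term, and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 23%. SE is the fitted log2 fold change divided by the square root of the F statistic. CPM values use TMM-scaled totals of the tested genes. The 30 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule names Psmd14, Cpa1, Krt19, Ins2, Cdkn1a, Ddit3 and Mki67. It adds the 4 protein-coding genes with the largest rise and the 4 with the largest fall among called genes of at least 10 CPM in the higher group whose groups do not overlap. It also takes the called members with the smallest p of each list, 2 for pathways and pancreatic cell types and 1 for other cell types and quality lists. Genes named outside it were chosen after their values were seen, either because a list had at most 5 called members in a direction or as said beside them. Some genes that the rule or a list would name are not reported here. Lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 30 lists. Camera called 5 lists higher and 11 lower, and 0 of these calls held with an estimated correlation. Fry, which tests whether a list's genes move on balance 1 way and does not compare them with other genes, called 5 lists: duct, injury, NF-kB, lymphocyte and neutrophil. Counts adjusted over the list alone use Benjamini-Hochberg within the list.

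The edgeR and camera steps were tested on simulated data for this comparison, with 18661 genes in the step, of which 100 were changed 2-fold and 100 4-fold. A separate list of 25 genes was also changed 2-fold. Outside that list, 36% of the 2-fold genes and 84% of the 4-fold genes were called in the right direction, with median absolute log2 fold changes of 1.02 and 1.98. Of 148 calls 20 were of unchanged genes, or 13.5%, above the nominal 5 in 100; with spreads simulated from the trend over expression the share was 3.57%. The share of wrong calls may thus exceed the threshold where genes differ in spread. The shares of right and of wrong calls also depend on how many genes change. The real comparison called 4224 of 19134 genes, far more than were changed in the simulation, so these shares do not carry over to it. Camera called a simulated list of 25 changed genes and not a list of 25 unchanged ones. The genes were simulated independently of each other. This therefore cannot show how camera behaves where list members vary together, as in the acinar enzyme list (estimated correlation 0.767).

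Alternatives were other scalings (DESeq2 size factors, none, upper quartile, factors without acinar enzymes), 2 other filters, stricter thresholds, DESeq2 1.42.0, limma-voom, the replicate number as a block, and leaving out each library in turn, where the lone library of a group is assumed to vary like the other group. A scaling without lymphocyte, adipocyte, immunoglobulin and T cell receptor genes and 8 further gene lists were added after seeing the data. Exon-level signal was not analysed here.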

Results

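RNA of mouse pancreas was sequenced in 4 libraries, 2 labelled control and 2 labelled knockout. The mice of both groups carried Pdx1-Cre, a recombinase active in the progenitors of acinar, duct and islet cells. Control mice had 1 floxed copy of poh1 and knockout mice had both copies floxed, so the comparison asks what loss of the remaining copy did to pancreatic gene expression. Poh1, now named Psmd14, encodes the deubiquitinase of the proteasome lid that removes ubiquitin chains from substrates. Total counts were 22875618 and 24635792 in control replicates 1 and 2, and 27470926 and 27849730 in knockout replicates 1 and 2. Values are given as CPM, read counts scaled to a common library size, in which 1 count was worth 0.0342 to 0.0455 CPM. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these samples, which may be technical. Values below are mean CPM ± SD or log2 fold change ± SE, knockout minus control, with n = 2 libraries per group.

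Psmd14 RNA was not lower in the libraries labelled knockout. The gene (GRCm38 chromosome 2, 61711694 to 61800376, plus strand) had 1354 and 1265 counts in control replicates 1 and 2, and 1839 and 1906 in the libraries labelled knockout. This was 57.3 ± 6.13 CPM in controls and 65.6 ± 0.444 CPM in the libraries labelled knockout. The log2 fold change was 0.20 ± 0.11, with a 95% interval from −0.09 to 0.48 (edgeR adjusted p = 0.259). The Psmd14 counts therefore give no support to the knockout label. They do not refute it either, since deletion limited to Pdx1-Cre lineage cells may weigh little in RNA of the whole tissue. Every direction below is a direction between labels. The counts are per gene, so they cannot show whether part of the transcript was missing, and the position of the floxed part is not given in the sources used here. Among 32 other subunits of the proteasome core and regulator, Psmd8 was the 1 gene past the threshold and fell (−0.70 ± 0.15, edgeR adjusted p = 0.0335). None passed when adjusted over the list alone, where 2 members had an unadjusted p under 0.05, DESeq2 called 2 lower and limma-voom 1. The median of this list was −0.18 (camera adjusted p = 0.0124; adjusted p = 0.89 with an estimated correlation). That camera call was lost without control replicate 1 (adjusted p = 0.284), without knockout replicate 1 (0.068), with DESeq2 (0.0705) and without scaling (0.0692). Without control replicate 2 it was stronger (camera adjusted p = 3.5e-05), with a median of −0.30 and 3 members lower, whereas the median was −0.05 without control replicate 1. Psmd8 itself was not called without control replicate 1 (edgeR adjusted p = 0.0584), knockout replicate 1 (0.0626) or knockout replicate 2 (0.0709). The 20 assembly factors and activators had a median of −0.09, whose sign changed without scaling (camera adjusted p = 0.331). edgeR and limma-voom called 0 of them, as did DESeq2, and 3 had an unadjusted p under 0.05.

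**Figure D1:**
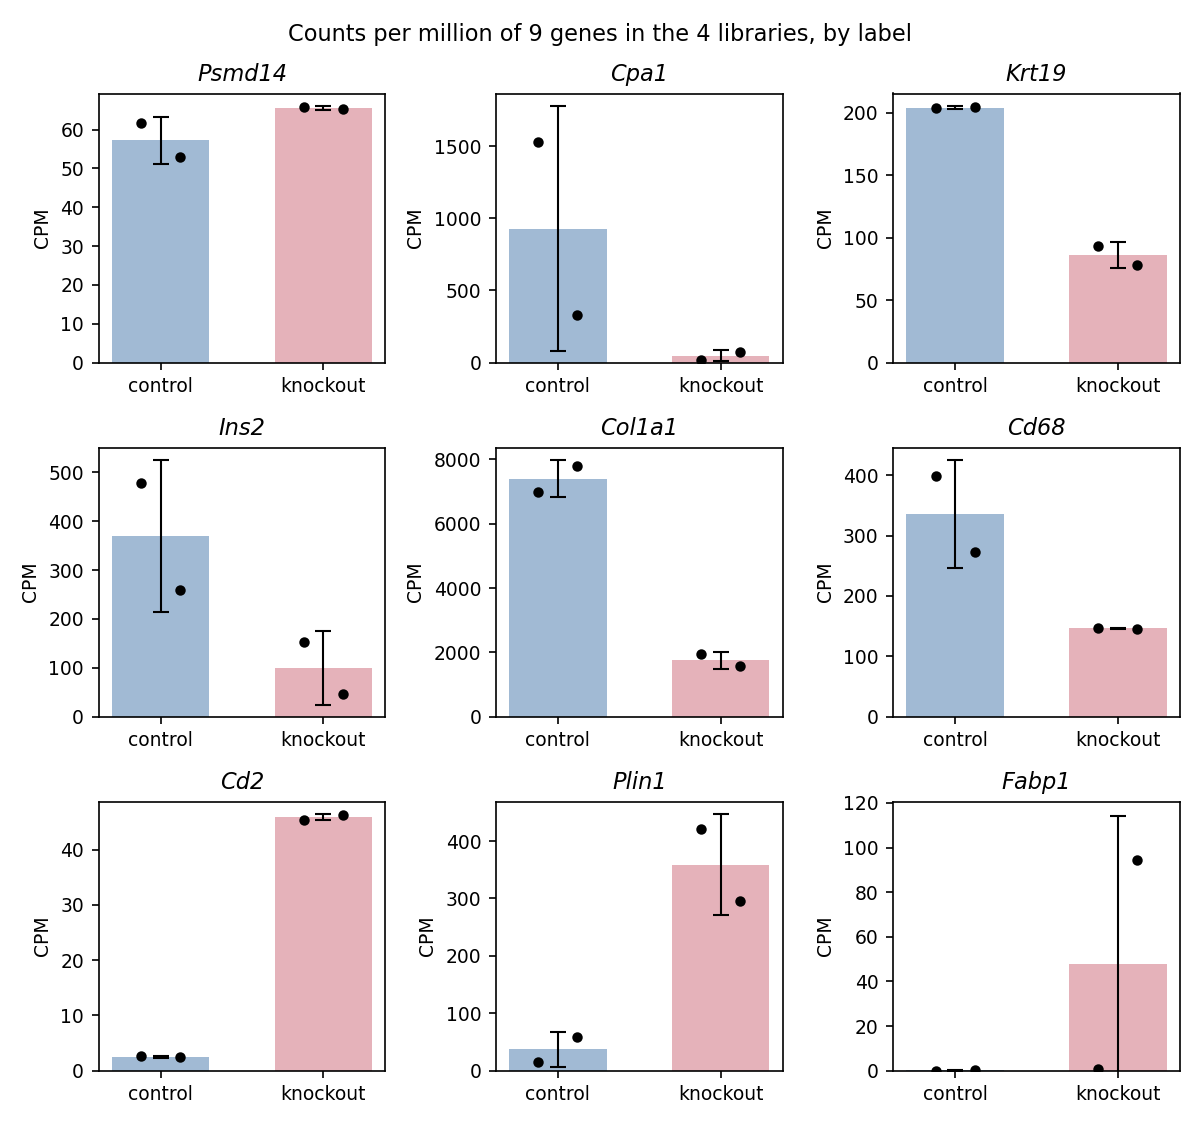
Normalised read counts (CPM) of 9 genes, with 1 point per library, bars at the mean of the 2 libraries of each label and error bars of 1 SD. Psmd14 was 57.3 CPM in controls and 65.6 CPM in the libraries labelled knockout, and the Fabp1 signal of the latter came from knockout replicate 2 (94.6 CPM) and not replicate 1 (0.788 CPM).

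The libraries labelled knockout held more RNA of lymphocyte and fat genes and less RNA of exocrine, duct, islet, macrophage and matrix genes than controls. Of 19134 genes tested, 2320 were higher and 1904 were lower in the libraries labelled knockout (edgeR adjusted p under 0.05), and 1586 and 903 of these changed at least 2-fold. Immunoglobulin genes made up 182 of the higher genes, out of 215 tested, and T cell receptor genes 44, out of 52 tested. The count filter admits genes expressed in 1 group only, so these numbers of tested genes can favour genes that rose. The largest rises chosen by the fixed rule were Ucp1, the uncoupling protein of brown and beige fat, Il22ra2, a soluble interleukin 22 receptor, Dsc3, a desmosomal cadherin, and Fgf23, a phosphate-regulating hormone. Ucp1 (chromosome 8, 83290352 to 83298452) had 2 counts in controls and 738 in the libraries labelled knockout, a ratio of 296 with a 95% counting interval from 81.8 to 2452. Il22ra2 (chromosome 10, 19621998 to 19634681) went from 0.091 ± 0.129 to 21.9 ± 3.46 CPM, Dsc3 (chromosome 18, 19960930 to 20002351) from 0.558 ± 0.275 to 78.8 ± 23.2 CPM, and Fgf23 (chromosome 6, 127072902 to 127081408) from 0.091 ± 0.129 to 11.1 ± 2.43 CPM. The largest falls were Gm10334, Prss1 and Gm5771, trypsinogens of 1 cluster on chromosome 6 (41392356 to 41463786), and Serpini2, a serpin of acinar cells (chromosome 3, 75242370 to 75270078). Their log2 fold changes were −7.63 ± 1.79, −7.51 ± 1.78, −7.21 ± 1.55 and −7.24 ± 1.32. The trypsinogens are near-identical copies whose shares of reads are uncertain. All 4 were much higher in control replicate 1 than 2 (Prss1 122 against 6.78 CPM), and limma-voom called none of them (adjusted p from 0.194 to 0.342). Leaving out control replicate 1 ended the calls of Ucp1 (edgeR adjusted p = 0.057), Gm10334 (0.16), Prss1 (0.126) and Gm5771 (0.0693). Without scaling beyond the library total the split was 2827 higher and 1527 lower, or 64.9% of calls higher against 54.9%, and the median of all genes shifted by 0.0987. Without control replicate 1 far fewer genes were called, but a lost call need not mean a changed difference. Of the named genes that lost their call, some kept their log2 fold change, such as Gstm1 (0.86, and 0.87 without that library) and Ddit4 (−0.71 and −0.72). Others shrank, such as Cpa1 (−4.27, and −2.77 without that library) and Prss1 (−7.51 and −4.27).

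**Figure D2:**
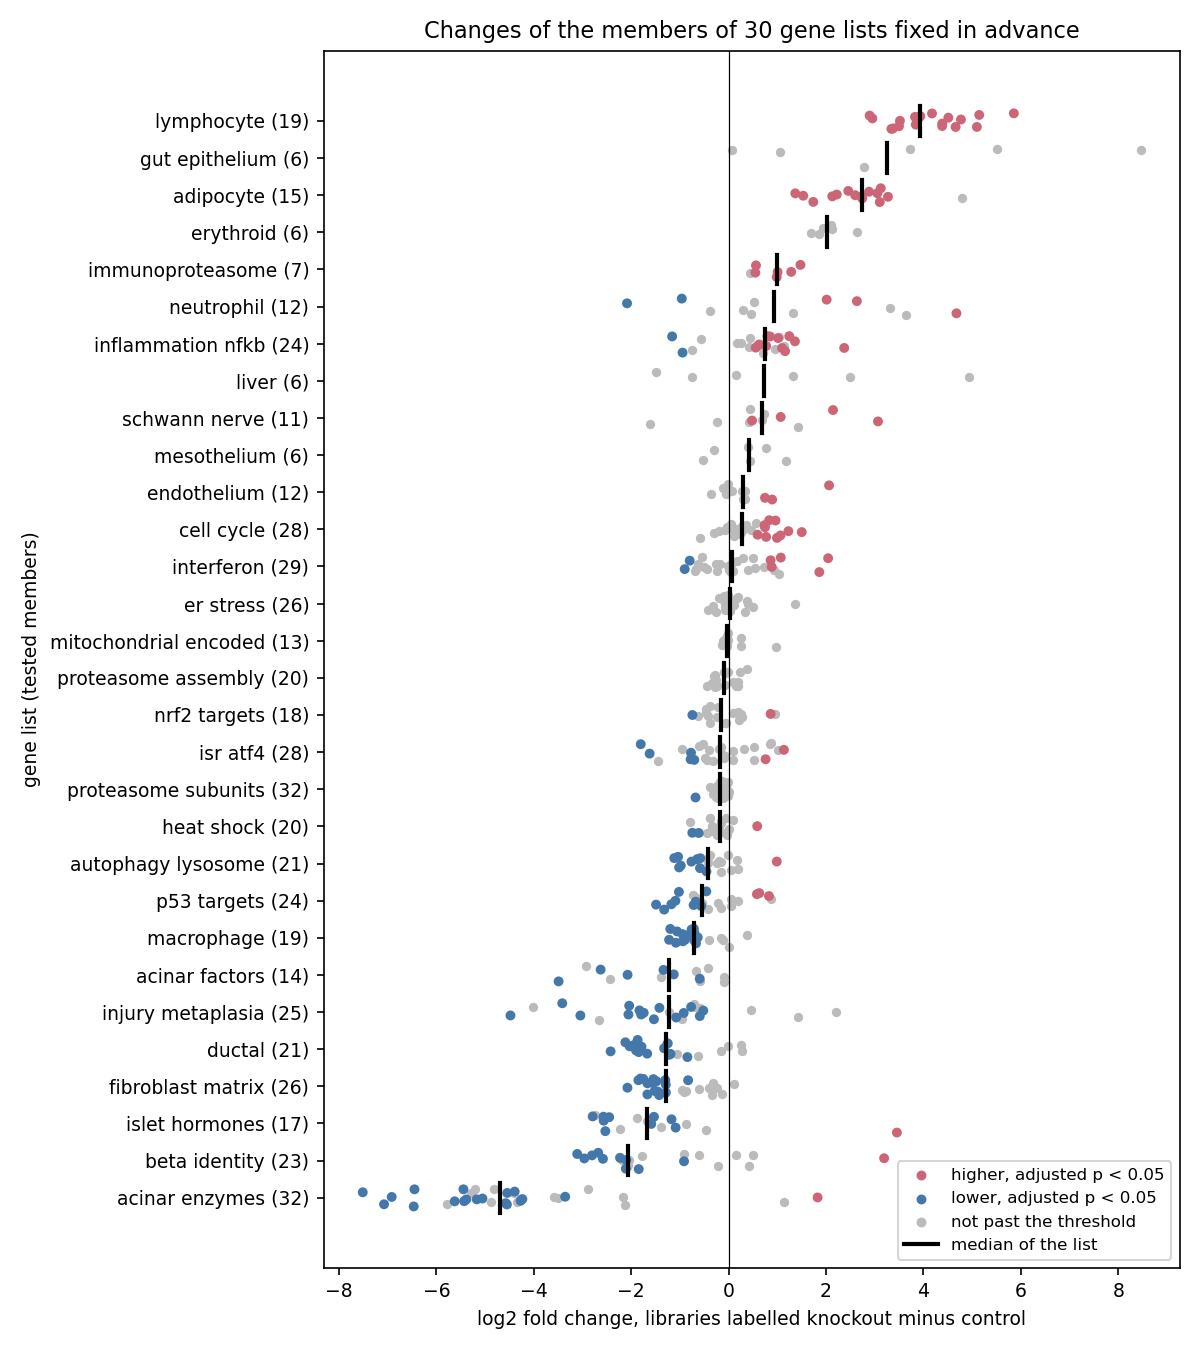
Log2 fold change (libraries labelled knockout minus control) of each tested member of the 30 gene lists chosen before the data were examined, with 1 point per gene, coloured where the edgeR adjusted p was under 0.05, and a black line at each list's median. The medians run from −4.69 for acinar enzymes to 3.94 for lymphocyte markers.

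Acinar digestive enzymes were lower in the libraries labelled knockout. Of 32 enzymes and granule proteins tested, 18 fell, 1 rose and 13 did not pass (edgeR), and adjusted over the list alone 27 fell and 2 rose. Their median log2 fold change was −4.69 (quartiles −5.43 and −4.08; camera adjusted p = 1.55e-06; adjusted p = 0.673 with an estimated correlation). Cpa1, carboxypeptidase A1, went from 928 ± 847 to 48 ± 39.2 CPM (−4.27 on the log2 scale, edgeR adjusted p = 0.0399), and Gp2, a zymogen granule membrane protein, from 68.6 ± 56.4 to 1.56 ± 0.692 CPM (−5.45 ± 0.80, edgeR adjusted p = 0.013). The control libraries differed, with Cpa1 at 1527 CPM in control replicate 1 and 329 CPM in control replicate 2. The gene that rose was Amy1, the salivary and liver amylase (12.3 ± 0.819 to 43.6 ± 10.7 CPM, edgeR adjusted p = 0.00765), which shares sequence with the pancreatic amylases. The whole list took 1.21 ± 1.15% of counts in controls and 0.0781 ± 0.0588% in the libraries labelled knockout. Whole pancreas RNA usually holds far more of these enzymes, and the labels do not say whether the control tissue was healthy or how it was dissected, so the fall is measured from a low control level of unknown cause. The most abundant transcript of neither group was a digestive enzyme, with the collagen gene Col3a1 first at 9279 ± 1510 CPM in controls and the complement gene C3 first at 5239 ± 412 CPM in the libraries labelled knockout. Regulators of acinar identity fell with the enzymes in 6 of 14 cases, and 8 fell when adjusted over the list alone (median −1.23; camera adjusted p = 0.00103; adjusted p = 0.564 with an estimated correlation). They included the transcription factors Foxa2 (−2.08 ± 0.22, edgeR adjusted p = 0.00662) and Foxa3 (−2.63 ± 0.53, edgeR adjusted p = 0.0275). Lymphocyte markers moved the other way in the same libraries (median 3.94), as did adipocyte markers (2.74). The enzyme median was −2.63 with 3 members lower without control replicate 1, and 1 regulator was lower without control replicate 1 or without control replicate 2; 28 and 31 enzymes were lower without knockout replicates 1 and 2. The calls of Cpa1 (edgeR adjusted p = 0.149), Foxa3 (0.143) and Amy1 (0.0619) were lost without control replicate 1, as were those of Cpa1 (0.0555) and Foxa3 (0.0732) without control replicate 2; limma-voom called 7 enzymes lower and did not call Gp2 (0.0573).

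**Figure D3:**
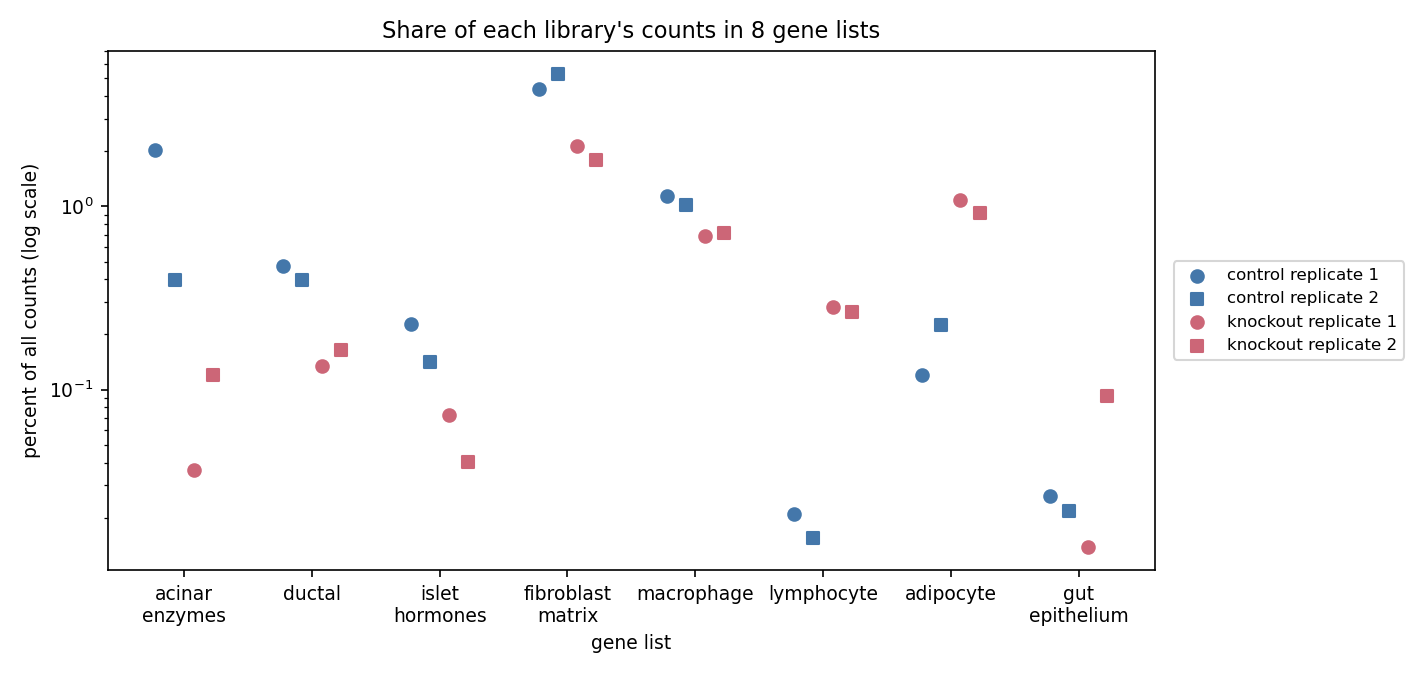
Percent of each library's counts (log scale) taken by 8 gene lists, with 1 symbol per library, circles for replicate 1 and squares for replicate 2, and colour by label. Lymphocyte and adipocyte genes took 0.274% and 0.998% of counts on average in the libraries labelled knockout, against 0.0183% and 0.173% in controls.

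Duct markers were also lower in the libraries labelled knockout. Of 21 tested, 14 fell and 7 did not pass, and 15 fell when adjusted over the list alone (edgeR; median −1.28, quartiles −1.87 and −0.85; camera adjusted p = 5.83e-07; adjusted p = 0.564 with an estimated correlation). The keratin Krt19 (chromosome 11, 100140810 to 100148665) went from 204 ± 1.02 to 85.9 ± 10.4 CPM (−1.25 ± 0.12, edgeR adjusted p = 0.00567). Krt7, another duct keratin, fell by 1.94 ± 0.14 and Cldn4, a tight junction claudin, by 2.42 ± 0.16 on the log2 scale (edgeR adjusted p = 0.00291 and 0.00241). Genes induced in injured or metaplastic acinar tissue were lower as well, with 15 of 25 down and 10 not passing, and 19 lower and 1 higher when adjusted over the list alone. Their median was −1.23 (camera adjusted p = 1.55e-06; adjusted p = 0.564 with an estimated correlation). Sox4, a transcription factor of epithelial remodelling, went from 312 ± 25.2 to 93.1 ± 1.17 CPM, and Tnfrsf12a, the receptor of the cytokine TWEAK, from 80.1 ± 5.17 to 22.5 ± 3.72 CPM (edgeR adjusted p = 0.00252 and 0.00384). Beside these, the matrix list had a median of −1.30 and the lymphocyte list of 3.94. When control replicate 1 was left out, the duct median was −1.25 and the injury median −0.97. Some members were much higher in knockout replicate 2, which carried intestinal genes (below), than in knockout replicate 1. Krt20 was at 83.1 against 6.45 CPM and Reg3g at 374 against 6.16 CPM. Without knockout replicate 2 the duct median was −1.76 and the injury median −1.67.

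Islet genes were lower too, with exceptions. Of 17 hormones and granule proteins 9 fell, 1 rose and 7 did not pass (edgeR), and 15 fell and 1 rose when adjusted over the list alone. The median was −1.67 (camera adjusted p = 7.21e-05; adjusted p = 0.564 with an estimated correlation). Somatostatin, Sst, went from 29.1 ± 12.3 to 5.02 ± 0.0122 CPM (−2.53 ± 0.33, edgeR adjusted p = 0.0101), and the granule protein Scg2 from 87.6 ± 25.4 to 30.3 ± 2.5 CPM (−1.53 ± 0.22, edgeR adjusted p = 0.0123). Insulin, Ins2, was 369 ± 155 CPM in controls and 100 ± 75.6 CPM in the libraries labelled knockout and did not pass (−1.88 ± 0.62, edgeR adjusted p = 0.0876). Ins2 did pass with the replicate number as a block (edgeR adjusted p = 0.00894). Its log2 fold change was −2.99 without knockout replicate 1 and −1.26 without knockout replicate 2. The gene that rose was the appetite hormone Ghrl, at 1 ± 0.205 CPM in the libraries labelled knockout and 0.0855 ± 0.0566 CPM in controls; its call was lost without control replicate 1, control replicate 2 or knockout replicate 1. Of 23 islet transcription factors and glucose-sensing genes, 10 fell, 1 rose and 12 did not pass, and 14 fell and 1 rose when adjusted over the list alone. The median of this list was −2.06 (camera adjusted p = 9.12e-05; adjusted p = 0.608 with an estimated correlation). The gene that rose was Ffar1, a fatty acid receptor (3.19 ± 0.30, edgeR adjusted p = 0.00517). Lymphocyte markers, with a median of 3.94, moved the other way in the same libraries. Without control replicate 1, 2 hormone genes and 0 of the transcription and sensing genes were lower. Without control replicate 2, 5 of each list were lower, without knockout replicate 1 the second list had 17 lower and a median of −2.84, and without knockout replicate 2 the first had 15 lower and the second a median of −1.39.

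Lymphocyte markers rose as a whole in the libraries labelled knockout. All 19 tested T, B and plasma cell genes were higher, also when adjusted over the list alone (edgeR; median 3.94, quartiles 3.51 and 4.59; camera adjusted p = 2.84e-14; adjusted p = 0.564 with an estimated correlation). Cd2, an adhesion receptor of T cells, went from 2.53 ± 0.15 to 45.9 ± 0.559 CPM (4.18 ± 0.15, edgeR adjusted p = 0.00153). Inflammatory cytokines and NF-kB targets rose in 12 of 24 cases and 2, Il1rn and Lif, fell; adjusted over the list alone 14 rose and 3 fell (median 0.74; camera adjusted p = 0.000637; adjusted p = 0.564 with an estimated correlation). Ccl5, a T cell chemokine, rose by 2.37 ± 0.18 and Tnfaip3, a brake on NF-kB signalling, by 1.36 ± 0.12 (edgeR adjusted p = 0.0033 and 0.0044). The immunoproteasome and peptide transport genes rose in 6 of 7 cases, and in 7 when adjusted over the list alone (median 0.99; camera adjusted p = 0.00224; adjusted p = 0.608 with an estimated correlation). Psmb9 went from 42.8 ± 3.66 to 119 ± 24 CPM and Psmb8 from 49.6 ± 2.62 to 99.5 ± 12.9 CPM (edgeR adjusted p = 0.00769 and 0.0091). Proliferation genes rose in 10 of 28 cases, and adjusted over the list alone 11 rose and 1 fell (median 0.27; camera adjusted p = 0.00196; adjusted p = 0.564 with an estimated correlation). Mcm5, a replication helicase subunit, rose by 1.23 ± 0.11 and Mki67 by 0.83 ± 0.19, and the cyclin Ccnd1 went from 29.5 ± 6.02 to 83.7 ± 8.43 CPM (edgeR adjusted p = 0.00464, 0.0388 and 0.00784). The higher genes without control replicate 1 numbered 6 in the NF-kB, 0 in the immunoproteasome and 4 in the proliferation list, and Psmb9 (edgeR adjusted p = 0.0688), Psmb8 (0.069) and Mki67 (0.163) were lost. Without control replicate 2 the immunoproteasome list had 2 and the proliferation list 6 higher, and Mki67 was lost without control replicate 2 (edgeR adjusted p = 0.0754) or knockout replicate 1 (0.0637).

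Macrophage markers, in contrast, were lower in the libraries labelled knockout. Of 19 tested, 14 fell and 5 did not pass, and adjusted over the list alone 15 fell and 1 rose (edgeR; median −0.71, quartiles −0.94 and −0.52; camera adjusted p = 1.82e-05; adjusted p = 0.564 with an estimated correlation). The chemokine receptor Cx3cr1 went from 134 ± 1.84 to 63.1 ± 0.649 CPM (−1.08 ± 0.09, edgeR adjusted p = 0.0039). Neutrophil markers went both ways, with Cxcr2, Elane and Mpo higher, Csf3r and Retnlg lower, and 7 of 12 not passing; adjusted over the list alone 4 rose and 2 fell (median 0.93; camera adjusted p = 0.0873). Csf3r, the receptor of granulocyte colony-stimulating factor, fell by 0.96 ± 0.10 (edgeR adjusted p = 0.00589). The neutrophil median depended on the filter, at 0.53 with a filter on mean counts and 1.33 without a low-count filter. The share of counts of this list was not higher, at 0.0215 ± 0.00194% in controls and 0.0171 ± 0.00215% in the libraries labelled knockout. Of 29 interferon-stimulated genes 5 rose (among them Ifi27l2a, Cxcl10, Irf1 and Cxcl9), 2 fell (Ifit1 and Ifit3) and 22 did not pass, and adjusted over the list alone 5 rose and 5 fell. The interferon median was 0.06, although camera placed the list as lower (adjusted p = 0.992). Ifi27l2a rose by 0.86 ± 0.14 and Ifit1 fell by 0.90 ± 0.15 (edgeR adjusted p = 0.0163 and 0.0166). Without control replicate 1, macrophage genes had 4 lower, the interferon list 0 called (Ifi27l2a edgeR adjusted p = 0.0646, Ifit1 0.0835), and the neutrophil list 0 higher and a camera adjusted p of 0.0399. Without control replicate 2, 1 interferon gene was higher and Ifit1 was lost (edgeR adjusted p = 0.072); 8 macrophage genes were lower without knockout replicate 1 and 8 without knockout replicate 2, 10 interferon genes were higher without knockout replicate 1, and 7 were lower without knockout replicate 2. DESeq2 called 5 interferon genes lower, and limma-voom and a filter on mean counts left 3 higher.

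Fibroblast and matrix genes were lower and adipocyte genes higher in the libraries labelled knockout. Of 26 fibroblast and matrix genes, 16 fell and 10 did not pass, and 19 fell when adjusted over the list alone (edgeR; median −1.30, quartiles −1.55 and −0.67; camera adjusted p = 2.53e-08; adjusted p = 0.564 with an estimated correlation). Postn, a matrix protein of activated fibroblasts, went from 1763 ± 48.5 to 524 ± 4.64 CPM (−1.75 ± 0.14, edgeR adjusted p = 0.00373). Of 15 adipocyte genes, 14 rose, and all 15 did when adjusted over the list alone (median 2.74, quartiles 2.17 and 3.08; camera adjusted p = 1.55e-06; adjusted p = 0.564 with an estimated correlation). Pparg, the master regulator of fat cells, went from 18.2 ± 0.118 to 52.5 ± 1.71 CPM (1.53 ± 0.11, edgeR adjusted p = 0.00308). The adipocyte median was 2.10 without control replicate 1 and 3.65 without control replicate 2. Endothelial markers rose in 3 of 12 cases, Cldn5, Pecam1 and Kdr, also when adjusted over the list alone (median 0.29; camera adjusted p = 0.224). Their median was 0.01 without control replicate 1 and 0.59 without control replicate 2. Cldn5, a tight junction claudin of vessels, rose by 2.06 ± 0.26 (edgeR adjusted p = 0.00959). Nerve and Schwann cell markers rose in 4 of 11 cases, among them Mbp and Cdh19, also when adjusted over the list alone (median 0.69; camera adjusted p = 0.137). With control replicate 1 left out edgeR called 0 nerve genes higher. Camera called the endothelial list (adjusted p = 0.0173) and the nerve list (0.0338) without control replicate 2, and the nerve list without knockout replicate 1 (0.00762), where 7 nerve genes were higher; 3 nerve genes were lower without knockout replicate 2.

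Called members of the integrated stress response, heat shock and NRF2 lists went both ways. edgeR and limma-voom called 0 of 26 endoplasmic reticulum chaperone and degradation genes (median 0.03; camera adjusted p = 0.942); DESeq2 called 1 higher and 1 lower, and 2 had an unadjusted p under 0.05. The sign of this median turned without control replicate 2 (−0.11) and without knockout replicate 1 (−0.09), and edgeR called 1 of these genes lower without control replicate 2 and 3 higher without knockout replicate 2. Of 28 targets of the integrated stress response, 2 rose (Slc7a11 and Psat1), 5 fell (Aldh1l2, Ddit4, Nupr1, Bbc3 and Atf3) and 21 did not pass, with 5 up and 8 down when adjusted over the list alone (median −0.18; camera adjusted p = 0.257, but 0.0081 without control replicate 2). Of these targets 0 rose and 2 fell without control replicate 1, 0 rose without control replicate 2, 3 fell without knockout replicate 1 and 4 rose without knockout replicate 2. Without scaling the balance turned, with 5 higher and 3 lower, and DESeq2 called 5 higher and 7 lower. Aldh1l2, a mitochondrial folate enzyme, fell by 1.62 ± 0.23, and Ddit4, an inhibitor of mTORC1, by 0.71 ± 0.11 (edgeR adjusted p = 0.012 and 0.0155). Ddit3, which encodes CHOP, was 27.4 ± 5.35 and 18 ± 1.84 CPM in the 2 groups and did not pass (edgeR adjusted p = 0.0761), though it did with DESeq2 (adjusted p = 0.0427). Of 20 heat shock genes Hspd1 rose (0.59 ± 0.12, edgeR adjusted p = 0.0298) and Bag3 (−0.75 ± 0.10, edgeR adjusted p = 0.0101) and Hspb8 fell, as they did when adjusted over the list alone (median −0.18; camera adjusted p = 0.052). Camera called the heat shock list without control replicate 2 (adjusted p = 0.0173), without knockout replicate 1 (0.0226), with limma-voom (0.0334), with a filter on mean counts (0.049) and without a low-count filter (0.0193). Without knockout replicate 1, 4 heat shock genes were lower and 3 NRF2 targets higher; DESeq2 called 4 heat shock genes lower, and 2 NRF2 targets higher and 3 lower. Of 18 NRF2 targets Gstm1 rose (0.86 ± 0.11, edgeR adjusted p = 0.00962) and Ftl1 fell (−0.74 ± 0.18, edgeR adjusted p = 0.0453); Gstm1 alone passed when adjusted over the list alone (median −0.15; camera adjusted p = 0.532). Ftl1 lost its call without scaling (edgeR adjusted p = 0.0581) and under a filter on mean counts (0.0522). With control replicate 1 left out the calls of Ddit4 (edgeR adjusted p = 0.073), Bag3 (0.0525), Hspd1 (0.0705), Gstm1 (0.0504) and Ftl1 (0.0676) were lost. Ddit4 (0.0575) and Hspd1 (0.077) were lost without control replicate 2, Ddit4 (0.0634), Hspd1 (0.0506) and Ftl1 (0.0674) without knockout replicate 1, and Hspd1 (0.152) and Ftl1 (0.11) without knockout replicate 2 (all edgeR adjusted p).

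Targets of p53 and genes of autophagy and lysosomes were mostly lower among those that changed. Of 24 p53 targets 9 fell, 3 rose (Ptp4a3, Rrm2b and Fas) and 12 did not pass, with 15 down and 4 up when adjusted over the list alone (edgeR; median −0.55; camera adjusted p = 0.00967; adjusted p = 0.608 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, went from 139 ± 29.4 to 49.6 ± 5.49 CPM (−1.49 ± 0.18, edgeR adjusted p = 0.00853). Zmat3, an RNA-binding p53 effector, fell by 1.09 ± 0.11 and the kinase Plk2 by 1.02 ± 0.11 (edgeR adjusted p = 0.00634 and 0.00656). Of 21 autophagy and lysosome genes 9 fell, Optn rose and 11 did not pass, with 10 down and 1 up when adjusted over the list alone (median −0.42; camera adjusted p = 0.00224; adjusted p = 0.564 with an estimated correlation). Ctsd, a lysosomal protease also abundant in macrophages, went from 1116 ± 155 to 515 ± 22.3 CPM, and Wipi1, an autophagosome factor, from 116 ± 2.54 to 58.5 ± 6.18 CPM (edgeR adjusted p = 0.0125 and 0.00765). The macrophage list fell beside these lists, with a median of −0.71. Leaving out control replicate 1 left 3 p53 targets and 4 autophagy and lysosome genes lower and 1 p53 target higher; 1 was higher also without control replicate 2 or knockout replicate 2, where 4 autophagy and lysosome genes were lower.

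With all 4 libraries and the main settings camera called none of the intestinal, hepatocyte, red cell and mesothelial lists, but 1 library carried intestinal genes. Of 11 intestinal epithelium genes 6 had enough counts to test, and edgeR and limma-voom called 0 of them, DESeq2 called 2 higher, and 2 had an unadjusted p under 0.05 (median 3.26; camera adjusted p = 0.49). Fabp1, the fatty acid binding protein of enterocytes, was at 0 and 0.251 CPM in controls, 0.788 CPM in knockout replicate 1 and 94.6 CPM in knockout replicate 2. Slc5a1, the intestinal glucose transporter, was at 80.4 CPM in knockout replicate 2 and at most 7.41 CPM elsewhere. Apob, named after its values were seen and expressed by intestine and liver, was at 190 CPM in knockout replicate 2, 0.43 CPM in knockout replicate 1, and 1.41 and 4.77 CPM in controls. Without knockout replicate 1 edgeR called 10 intestinal genes higher (camera adjusted p = 2.15e-08), and without knockout replicate 2 it called 3 lower, with a median of −0.44. Of the hepatocyte list 6 of 13 genes were tested. edgeR and limma-voom called 0 of them, DESeq2 called 1, and 2 had an unadjusted p under 0.05. The hepatocyte median was 0.74 (camera adjusted p = 0.942), 0.06 without knockout replicate 2 and −0.16 without knockout replicate 1. The whole list, untested members included, took 0.0691% and 0.128% of counts in knockout replicates 1 and 2. In control replicates 1 and 2 it took 0.00542% and 0.0223%. Of the red cell list 6 of 7 were tested, with 0 called by edgeR and limma-voom, 1 by DESeq2 and 3 at an unadjusted p under 0.05 (median 2.02; camera adjusted p = 0.0504, but 0.0293 with limma-voom, 0.049 with a filter on mean counts, 0.0278 without a low-count filter, 0.0109 without knockout replicate 1, where 6 were higher, and 0.0137 without control replicate 2). The most abundant globin, Hbb-bs, was at 16.2 and 67.6 CPM in controls and 85 and 186 CPM in the libraries labelled knockout. Of the mesothelial list 6 of 7 were tested, with 0 called by edgeR and limma-voom, 1 by DESeq2 and 1 at an unadjusted p under 0.05 (median 0.42; camera adjusted p = 0.557); 2 were lower without knockout replicate 1 and 2 higher without knockout replicate 2. edgeR, DESeq2 and limma-voom called 0 of 13 mitochondrially encoded messenger RNAs, and 0 had an unadjusted p under 0.05; the median was −0.03, with a sign that differed under other scalings (camera adjusted p = 0.992).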

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

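The scaling without lymphocyte, adipocyte, immunoglobulin and T cell receptor genes was chosen after seeing the data; the other alternatives were set before. Higher genes numbered 2091 to 2865 and lower genes 1527 to 2447 over the other scalings, filters and tools, against 2320 and 1904. With an adjusted p under 0.01 they numbered 644 and 323, and 903 lower genes changed at least 2-fold, fewer because the threshold was stricter. Leaving out 1 library gave 702 to 2338 higher and 424 to 1696 lower genes, the lowest without control replicate 1, where 1093 of the 4224 calls were shared and had the same sign; fewer libraries leave fewer degrees of freedom, and why control replicate 1 mattered most was not tested. Deviations of same-numbered libraries correlated at 0.028 across genes, which gives no sign of pairing, though 2 pairs cannot exclude it. With the replicate block 1960 genes were higher and 1432 lower, 3180 of them shared with the unblocked calls. Ins2 then passed (edgeR adjusted p = 0.00894), and all 6 red cell genes were higher (camera adjusted p = 0.000226). Cpa1 (edgeR adjusted p = 0.0643), Mki67 (0.0577), Hspd1 (0.0645) and Ftl1 (0.0594) lost their calls with the block. It left 9 acinar enzymes lower, against 18. Psmd14 stayed above 0 and past no threshold in every fit (edgeR adjusted p from 0.118 to 0.601, DESeq2 0.382, limma-voom 0.268). No call among the 53 named genes and 30 fixed lists changed direction in any alternative. The lists added after seeing the data were run again under the other scalings, filters and tools and without each library, where camera lost neither the lymphoid stroma nor the thermogenic fat list; counts that moved are given beside each list. Of 53 named genes 20 lost their call without control replicate 1, 6 without control replicate 2, 5 without knockout replicate 1, 3 without knockout replicate 2, 5 with limma-voom and 4 with the block. All 16 list calls were lost with camera's estimated correlation and 12 with fry, and other list calls that changed with a library are given beside each list. Of 60 counts of list members, 16 moved by over 1.5 times with the replicate block, 15 with DESeq2 and 0 with the added scaling. More moved whenever 1 library was left out, and most without control replicate 1. Without scaling 1 gene each of the injury, macrophage, mesothelial and endoplasmic reticulum lists was called higher, against 0, and DESeq2 called 1 proliferation gene lower, against 0. Medians of lists that camera did not call changed sign without control replicate 1 for proteasome assembly (0.01), integrated stress response (0.01), NRF2 (0.04), interferon (−0.06) and mitochondrial genes (0.04), and for interferon also without knockout replicate 2 (−0.18). Ucp1 had 2 counts in controls, and of 11 intestinal and 13 hepatocyte genes 6 each had enough counts to test.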

Other observations

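The test of lymphoid stroma was set before the values of its tested genes were seen. Glycam1 was left out of that list because its value had been seen, so this test was not wholly independent of the data. The other tests, that of globin among them, and the 8 gene lists of this part were chosen after the results were seen.

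The 5 lists of this and the next paragraph given without camera hold genes already seen to change, so they are described by counts and are no independent evidence. Of 12 immunoglobulin constant genes, part of the immunoglobulin genes reported above, 11 rose (edgeR; median 4.64, or 4.59 with Ighe, absent from controls, at the bound of 3 counts over that group). Ighg2b went from 5.26 ± 1.91 to 569 ± 21.3 CPM (n = 2), whereas Ighm differed between the libraries labelled knockout, at 4278 and 1228 CPM, and did not pass (edgeR adjusted p = 0.0505). All 11 genes of the class II antigen presentation list rose (median 1.40), a list shared by B cells and other antigen-presenting cells, with H2-Ob going from 8.75 ± 0.548 to 164 ± 11.3 CPM (n = 2). Of 10 genes of germinal centre B cells and follicular T cells 7 rose, among them the T cell genes Icos and Pdcd1 and the p53 target Fas, S1pr2 fell, and Bcl6 (edgeR adjusted p = 0.155) and Rgs13 (0.147) did not pass (median 2.98); Cxcr5, a chemokine receptor of follicular B and T cells, went from 2.24 ± 0.564 to 57.7 ± 2.43 CPM (n = 2). Without control replicates 1 and 2 in turn edgeR called 6 and 7 constant genes and 3 and 4 germinal centre genes higher, and S1pr2 was not called without control replicate 1.

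Of 13 myofibroblast genes 9 fell in the libraries labelled knockout, among them Postn of the fibroblast and matrix list (edgeR; median −1.54), with Cthrc1 going from 89.5 ± 4.36 to 11.9 ± 1.15 CPM (n = 2). Of 14 genes of lipid-associated macrophages 10 fell, and Retnla and Lpl rose (median −1.01); Trem2 went from 131 ± 29.9 to 33.4 ± 0.825 CPM (n = 2). Of these, Spp1 is also in the duct list, Lgals3 in the injury list and Ctsd in the autophagy and lysosome list, all lower, and Lpl in the adipocyte list, which was higher. Of 7 thermogenic fat genes, a list that holds Ucp1 and was chosen after the adipocyte rise was seen, 5 rose (median 1.44, also with Elovl3 at its bound; camera adjusted p = 0.000592, 0.176 with an estimated correlation), Cidea from 2.39 ± 0.419 to 6.49 ± 1.33 CPM (n = 2). The adipocyte list had the higher median in the same libraries (2.74, 14 of 15 higher), but the thermogenic genes differed. Ucp1 (8.05), Elovl3 (7.22, with 0 CPM in controls) and Cox8b (4.42) lay above the adipocyte upper quartile of 3.08. Cidea (1.44), Ppargc1a (1.38), Cox7a1 (1.03) and Dio2 (−0.002) lay below its lower quartile of 2.17. A change beyond fat content is therefore neither shown nor excluded. With control replicate 1 left out edgeR called 6 myofibroblast and 6 lipid macrophage genes lower, and 1 of the latter and 0 thermogenic genes higher; 2 thermogenic genes were higher without control replicate 2.

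Psmd14 RNA was not lower in the libraries labelled knockout (log2 fold change 0.196). Deletion limited to Pdx1-Cre lineage cells may weigh little in tissue where these cells give little RNA: the pooled acinar, duct and islet genes had a median log2 fold change of −2.33, with 41 of 70 lower and 2 higher. This value pools lists reported above, whose values were seen first, so it is no separate test. It goes with less lineage RNA in the libraries labelled knockout, but it does not show that deletion took place. Transcripts without the deleted part that are still counted, and swapped labels, cannot be told apart from this: gene-level counts hold no exon signal, and the interval of control minus knockout, from −0.48 to 0.09, includes 0. A true effect of the genotype also stays open, as untested.

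The rise of lymphocyte genes was set against 3 sources of lymphoid RNA. Residual blood is argued against: summed globin rose by 182 CPM and the lymphocyte list by 2468 CPM, a ratio of 0.0736, although globin dominates whole blood RNA. Organised lymphoid tissue, such as a lymph node in the sampled piece or follicles in the gland, may contribute: the lymphoid stroma genes had a median of 1.36, with Ccl19, Ccl21a, Enpp2 and Madcam1 higher out of 7 (camera adjusted p = 0.000886, 0.176 with an estimated correlation), though edgeR called 1 without control replicate 1 and 2 without control replicate 2. Whether it lay inside or beside the gland is open, as is spleen tissue, which cannot be told apart: its stroma and red cell genes had a median of 2.02, but of 8 genes Spic alone was called. Nkx2-3 of the spleen stroma went from 27.6 ± 4.81 to 19.7 ± 3.33 CPM (n = 2; −0.49, edgeR adjusted p = 0.137), the stroma median turned where Tlx1 could be tested (−0.33 without knockout replicate 1), and 6 red cell genes were higher without knockout replicate 1. Inflammation of the gland after poh1 loss stays open, as untested.

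Markers of other cell types moved apart. A smaller acinar share that raised all other types alike is argued against, since the lymphocyte and matrix medians lay 5.23 log2 units apart with opposite signs. Scaling is argued against by the same value, since a factor moves all genes of a library alike. Both medians are reported above and had been seen when this comparison was set, so the comparison is no separate test. Fat from outside the gland cannot be told apart from fat within it, since the adipocyte median of 2.74 holds no value that separates them; replacement of the gland by fat stays open, as untested.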
